A study of Caenorhabditis elegans with 6 samples.

How the data were processed

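Whole Caenorhabditis elegans animals were profiled by RNA sequencing at the L4 larval stage after infection with Pseudomonas aeruginosa PA14, a bacterial pathogen that kills the animals. Per the labels, 3 libraries came from unc-30(ok613) mutants (strain VC295) and 3 from the wild-type strain N2. Per the labels' protocols, about 40 gravid adults laid eggs for 3 h on 10 cm plates with Escherichia coli OP50, the offspring grew at 20 °C, and infection lasted 4 h at 25 °C. Total RNA was extracted and treated with DNase, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

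The deposited values were raw read counts per WormBase gene, made by the authors with HTSeq, per the submitters' processing notes, which also name DESeq2. The aligner, genome build, annotation release, strand setting and version of each tool are not given in the sources used here. Each table listed 46911 gene identifiers with no summary lines. Symbols were looked up by identifier in an Ensembl release 115 annotation of WBcel235, where 44059 identifiers had a match and 2852 did not; the latter kept their identifiers. Positions come from that annotation, which may differ from the one used for counting. Because the strand setting is unknown, reads of overlapping and antisense genes cannot be separated, and members of near-identical families (major sperm proteins, histones, neighbouring collagens and lectins) may share reads.

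The unc-30 libraries held 17493014, 21368376 and 17804171 counted reads and the wild-type libraries 22325809, 22399877 and 25257342. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. The intervals given below are over genes and do not measure the spread between libraries. Where a gene had 0 reads in every library of a group, its fold was bounded against a floor of 3 counts over that group.

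Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 14788 of 22193 genes with at least 1 read. Counts were scaled by the trimmed mean of M values (TMM), and CPM is relative to the scaled library size. Genotypes were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; a gene past it is described as called. Log2 fold changes are unc-30 minus wild type, and their standard error (SE) is the fold change divided by the square root of the F statistic. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used.

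Before the data were examined, 33 gene lists were fixed, 18 for pathways and 15 for developmental stage, tissue share or library make-up. Lists with at least 3 tested members were compared with all other genes by camera (limma) with a preset inter-gene correlation of 0.01, adjusted over 31 lists. The mitochondrial list matched 0 symbols and the male list had fewer than 3 tested members, so neither was tested in the main fit. The rule for named genes was also fixed then. It took unc-30, unc-25 and unc-47, then the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the groups. It added the 5 lowest p-values in each direction, then up to 2 called members in each direction for each list, or the member with the lowest p where none was called. Genes named outside that rule are said to be so.

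The alternatives were DESeq2 size factors, library totals, no low-count filter, a stricter filter (at least 10 CPM in at least 3 libraries), the replicate number as a block, each library left out in turn, DESeq2, limma-voom, an adjusted p under 0.01, an added limit of 2-fold, an estimated inter-gene correlation, and the rotation test fry. Scaling to the body wall muscle list and to the intestine list was added after seeing the data.

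The steps were tested on simulated counts drawn from the means and depths of these libraries. Of 97 genes changed by 1 on the log2 scale, 76.3% were recovered, and of 100 changed by 2, 100% were. Among 14389 unchanged genes, 23 were called. Of 3 shifted lists 3 were recovered, and 0 of 28 unshifted lists were called. Each simulated gene was drawn independently and few were changed. The simulation therefore does not test the preset correlation, or the scaling where most genes change.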

Results

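The series compared gene expression in infected unc-30(ok613) animals with that in infected wild-type animals. UNC-30 is a homeodomain transcription factor that sets the identity of D-type GABA motor neurons. The comparison asks which genes depend on unc-30 during exposure to P. aeruginosa. There were 3 libraries per genotype and no uninfected library was analysed here, so the response to infection itself was not measured.

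Libraries separated by genotype. The first principal component held 81.8% of the variance and placed the unc-30 libraries at -58, -67.9 and -45.2 and the wild-type libraries at 57.9, 54.5 and 58.8. The chi-square per degree of freedom was 10.6 to 21 between libraries of a genotype and 143 to 272 across genotypes, so no libraries were merged. The unc-30 libraries detected 17814, 18452 and 18234 genes, and the wild-type libraries 19193, 18907 and 19156.

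The unc-30 gene lies on chromosome IV at 13118977 to 13124406 (WBcel235). It had 13, 29 and 18 reads in the libraries labelled unc-30 and 23, 20 and 22 in those labelled wild type. Its level was 1.23 ± 0.35 CPM in the mutant and 0.78 ± 0.05 CPM in wild type (SD, n = 3 each, log2 fold change 0.67 ± 0.32 SE, edgeR adjusted p = 0.0775). With a library left out it ranged from 0.43 to 0.84, called higher only at the upper end (without unc-30 replicate 1, adjusted p = 0.0486), and it was 0.17 with library totals and -0.40 with muscle scaling. Counts over the whole gene do not separate deleted from retained exons, so they do not check the labels, and every direction here follows the labels.

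Infected unc-30 animals had lower yolk protein, oocyte and sperm transcripts and higher transcripts of cuticle collagens, moulting factors, neuropeptides, ribosomal proteins and many antimicrobial genes, though with muscle scaling, which lowers all genes, the medians of the ribosomal and antimicrobial lists fell below 0 while camera still called them higher than the other genes. These list calls rest on a preset correlation between genes, and none was kept with an estimated one. The rotation test fry, which does not compare a list with the other genes, kept all but the oocyte and sperm calls. Vitellogenin genes took 0.74 ± 0.228% of reads in unc-30 and 3.2 ± 0.0551% in wild type, and collagen genes 6.66 ± 0.344% and 5.1 ± 0.269% (SD, n = 3 each). Of 14788 tested genes, 9457 (64%) were called, 4571 higher and 4886 lower in unc-30. A change of at least 2-fold was seen for 1867 higher and 2193 lower genes. The groups did not overlap for 68.6% of tested genes, where chance gives 10%.

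The split between directions depended on scaling. TMM factors were 0.806 to 0.869 in unc-30 and 1.15 to 1.24 in wild type. With library totals the median of all genes moved by -0.51 on the log2 scale and 20.4% of calls were higher, against 48.3% with TMM; 2090 genes were higher and 8150 lower. Scaling to intestine genes moved the median by -0.64 and left 15.2% of calls higher, and scaling to muscle genes moved it by -1.08 and left 5.79% higher. Medians of lists below are relative to all genes under TMM, and a list test by camera compares a list with the other genes.

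**Figure D1:**
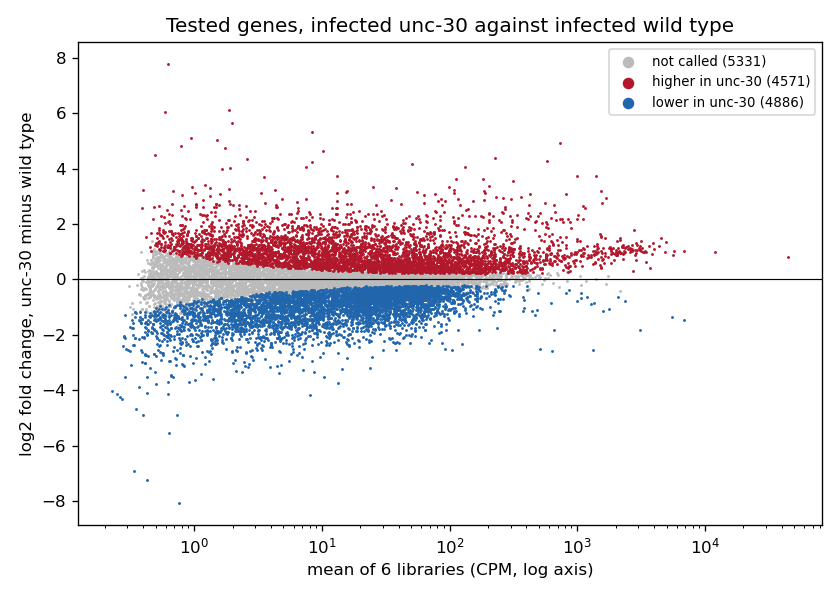
Log2 fold change (unc-30 minus wild type, TMM scaling) of each tested gene against its mean over 6 libraries in CPM on a log axis. Red points are the 4571 genes called higher, blue points the 4886 called lower and grey points the 5331 not called; the 4 called genes with 0 reads in a whole group are drawn at fitted values.

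GABA motor neuron genes moved in both directions. Of 10 tested members, 4 were higher, 2 lower and 4 not called, and the list was not shifted as a whole (median 0.20, camera adjusted p = 0.698, median -0.31 with library totals, -0.45 with intestine and -0.89 with muscle scaling, where 1 was higher and 7 lower). The gene for glutamic acid decarboxylase, unc-25, fell by 1.33 on the log2 scale (SE 0.15, edgeR adjusted p = 4.16e-06), from 14.8 ± 0.839 to 5.88 ± 0.849 CPM (SD, n = 3 each). The transthyretin-like gene ttr-39 had 37, 41 and 48 reads in wild type and 0 in each mutant library, at least 24-fold lower by a floor of 3 counts over the group. The neuropeptide genes flp-11 and flp-13 rose by 1.73 ± 0.12 and 1.38 ± 0.18 (SE), the latter not called with muscle scaling. Both also belong to the neuropeptide list, where 79 of 88 genes were higher and 0 lower under TMM (median 1.35), so their rise is not particular to GABA neurons. The vesicular GABA transporter gene unc-47 was at 0.727 ± 0.32 CPM in wild type (SD, n = 3), with a log2 fold change of -0.69 ± 0.54 SE (adjusted p = 0.284), and ranged from -1.82 (called, without unc-30 replicate 2, adjusted p = 0.0245) to -0.26 with a library left out, and was called lower with intestine (-1.33, adjusted p = 0.023) and muscle scaling (-1.78, adjusted p = 0.00321). Beside these, 7 of 16 pan-neuronal genes were higher and 1 lower (median 0.25, camera adjusted p = 0.0329, adjusted p = 0.449 with an estimated correlation), with that median at -0.25 with library totals, -0.39 with intestine and -0.82 with muscle scaling, where 3 were higher and 12 lower. The call was lost without WT replicate 2 (adjusted p = 0.0612).

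Of 8 GABA receptor genes, 5 were higher and 3 not called under TMM (median 0.65, camera adjusted p = 0.114). With muscle scaling 0 were higher and 3 lower (median -0.43), while camera called the list up against the other genes (adjusted p = 0.0246). The member lgc-38 rose by 1.10 ± 0.27 (SE) and was not called with library totals, where 1 member was higher.

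Genes that depend on the p38 kinase PMK-1, a central regulator of intestinal immunity, were higher than the other genes under each scaling, with a median below 0 under muscle scaling. All 12 tested members were called higher under TMM (median 1.01, camera adjusted p = 9.49e-06, adjusted p = 0.312 with an estimated correlation), and the median was -0.07 with muscle scaling. The infection response genes irg-5 and irg-4 rose by 1.94 ± 0.14 and 1.45 ± 0.14 (SE). With library totals 7 were higher and 1 lower, with intestine scaling 7 and 1, and with muscle scaling 2 and 5, while camera still called the list up against the other genes (adjusted p = 6.64e-05, 0.000127 and 0.00103). Tissue genes moved the same way under TMM: body wall muscle 15 of 17 higher (median 1.37), pharynx 11 of 13 higher and 1 lower (median 1.13), and intestine 7 of 14 higher (median 0.56, and -0.52 with muscle scaling, where pharynx had 1 higher and 5 lower and intestine 2 and 7). Their camera adjusted p-values were 2.49e-10, 0.00218 and 0.00419, and with an estimated correlation adjusted p = 0.312, 0.449 and 0.312.

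Other antimicrobial families rose beside those tissue genes under TMM, with medians below 0 under muscle scaling, where camera still called lysozymes, epidermal peptides and C-type lectins up against the other genes (adjusted p = 5e-06, 3.07e-06 and 1.29e-05). Lysozyme and saposin-like genes had 24 higher and 1 lower of 33 under TMM (median 0.85, camera adjusted p = 3.1e-06, adjusted p = 0.312 with an estimated correlation), with spp-12 and lys-6 at 3.34 ± 0.38 and 3.06 ± 0.34 (SE). With muscle scaling 5 were higher and 14 lower (median -0.22). Reads were few for spp-12, at 4, 4 and 6 in wild type and 30, 31 and 22 in unc-30. For lys-6 they were 13, 9 and 6 in wild type and 46, 53 and 37 in unc-30. Epidermal antimicrobial peptide genes had 23 higher and 1 lower of 29 under TMM (median 0.92, camera adjusted p = 3.1e-06, adjusted p = 0.44 with an estimated correlation), and 7 higher and 11 lower with muscle scaling (median -0.17). In that list cnc-3 rose by 1.94 ± 0.16 and fipr-13 fell by 1.78 (SE 0.25). C-type lectin genes were split, with 55 higher, 23 lower and 39 not called (median 0.50, camera adjusted p = 0.00344, adjusted p = 0.312 with an estimated correlation), and a median of -0.01 with library totals, -0.14 with intestine and -0.57 with muscle scaling, where 19 were higher and 58 lower. The lectin gene clec-72 rose by 2.82 ± 0.17, while clec-223 fell by 4.16 (SE 0.24) and clec-222, which may share its reads, fell by 3.39 (SE 0.29).

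Of 7 infection response genes in the ZIP-2 list, 4 were higher and 3 not called under TMM (median 0.92, camera adjusted p = 0.0885). With muscle scaling 0 were higher and 2 lower (median -0.16), while camera called the list up against the other genes (adjusted p = 0.026). The list was also called with library totals (adjusted p = 0.0425) and without unc-30 replicate 1 (adjusted p = 0.0499). The gene zip-2, a bZIP factor, rose by 1.29 ± 0.12 (SE) and was not called with muscle scaling. Of 14 pals genes, linked to intracellular infection, 1 was higher and 4 lower (median -0.38, camera adjusted p = 0.489), and with library totals, intestine and muscle scaling 0 were higher and 7, 8 and 14 lower. The lower member pals-33 fell by 1.83 (SE 0.47), with 18, 17 and 22 reads in wild type and 2, 5 and 2 in unc-30.

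Targets of the FOXO factor DAF-16 that it activates were mostly higher under TMM, 12 of 14 with 2 not called (median 1.03, camera adjusted p = 0.000228, adjusted p = 0.266 with an estimated correlation). With muscle scaling 2 were higher and 3 lower (median -0.04). The glyoxylate cycle gene icl-1 rose from 166.4 ± 27 to 813 ± 72 CPM (SD, n = 3 each, log2 fold change 2.29 ± 0.13 SE). Of 7 genes repressed when DAF-16 is active, 4 were higher and 1 lower (median 0.28, camera adjusted p = 0.631), with that median at -0.23 with library totals, -0.36 with intestine and -0.80 with muscle scaling, where 0 were higher and 5 lower. Under TMM the mean of -0.06 was opposite in sign to the median and camera. The member dod-23 fell by 2.32 (SE 0.17).

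Lipid genes changed in both directions apart from yolk. All 6 vitellogenin genes were lower under each scaling (median -2.16, camera adjusted p = 1.22e-06, adjusted p = 0.312 with an estimated correlation), and vit-3 fell from 1081 ± 109 to 182 ± 49 CPM (SD, n = 3 each). Fatty acid synthesis and desaturation had 7 higher, 7 lower and 5 not called (camera adjusted p = 0.732), with the median of 0.09 opposite in sign to camera and at -0.42, -0.55 and -0.98 with library totals, intestine and muscle scaling, where 1, 0 and 0 were higher and 13, 13 and 18 lower. The desaturase gene fat-7 fell by 2.05 (SE 0.17) and fat-5 fell by 1.21 (SE 0.15). Lipid breakdown genes had 23 higher and 7 lower of 47 (median 0.34, camera adjusted p = 0.0662), with a median of -0.16 with library totals, -0.31 with intestine and -0.74 with muscle scaling, where 7, 5 and 2 were higher and 19, 23 and 38 lower. They were called without WT replicate 1 (adjusted p = 0.0378). In that list acdh-7, an acyl-CoA dehydrogenase gene, rose by 1.61 ± 0.09 (SE) and cpt-5, a carnitine palmitoyltransferase gene, fell by 1.64 (SE 0.10).

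Detoxification genes had 47 higher, 23 lower and 66 not called (median 0.18, camera adjusted p = 0.176), and its median was -0.32, -0.46 and -0.90 with library totals, intestine and muscle scaling. With library totals 19 were higher and 54 lower, and camera called the list higher than the other genes, which fell further (adjusted p = 0.0403). The glutathione transferase gene gst-20 rose by 2.28 ± 0.13 and the glucuronosyltransferase gene ugt-63 fell by 2.24 (SE 0.24). Heat shock genes had 2 higher and 3 lower of 9 (median -0.06, camera adjusted p = 0.511), against 0 and 6 with library totals, 0 and 6 with intestine and 0 and 8 with muscle scaling, with hsp-16.41 down by a log2 change of -1.55 (SE 0.18). Endoplasmic reticulum stress genes had 7 higher and 2 lower of 16 (median 0.13, camera adjusted p = 0.0225, adjusted p = 0.516 with an estimated correlation), with a median of -0.38 with library totals, -0.51 with intestine and -0.95 with muscle scaling, where 1 was higher and 9 lower. The call was lost with library totals (adjusted p = 0.0926). The higher members pdi-2, a protein disulfide isomerase gene, and hsp-3 rose by 1.78 ± 0.12 and 1.26 ± 0.10 (SE), hsp-3 not being called with muscle scaling, while the sensor gene ire-1 fell by 0.79 (SE 0.10).

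Peptide hormone genes rose. Of 88 neuropeptide genes, 79 were higher, 0 lower and 9 not called (median 1.35, camera adjusted p = 1.02e-19, adjusted p = 0.312 with an estimated correlation), and the median stayed above 0 under each scaling, with 67 higher and 1 lower with library totals, 60 and 2 with intestine and 26 and 10 with muscle scaling. The gene nlp-12 rose by 2.35 ± 0.14 (SE), and the processing enzyme genes egl-21 and egl-3 by 1.68 ± 0.12 and 1.65 ± 0.11. Insulin-like genes had 15 higher and 2 lower of 23 under TMM (median 1, camera adjusted p = 0.00125, adjusted p = 0.312 with an estimated correlation), and ins-5 rose by 2.11 ± 0.23. With muscle scaling 7 were higher and 6 lower (median -0.08). Lists for other transmitter classes were not called under TMM. Cholinergic genes had 6 higher and 1 lower of 11 (median 0.97, camera adjusted p = 0.0776), and glutamate and monoamine genes 5 higher and 1 lower of 8 (median 0.72, camera adjusted p = 0.489). With muscle scaling the cholinergic list had 1 higher and 2 lower (median -0.11), and the glutamate and monoamine list 0 higher and 3 lower (median -0.36). The cholinergic list was called, pointing up, without unc-30 replicate 1 (adjusted p = 0.0342), with library totals (adjusted p = 0.0212) and with muscle scaling (adjusted p = 0.00575). The octopamine synthesis gene tbh-1 fell by 1.97 (SE 0.17).

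**Figure D2:**
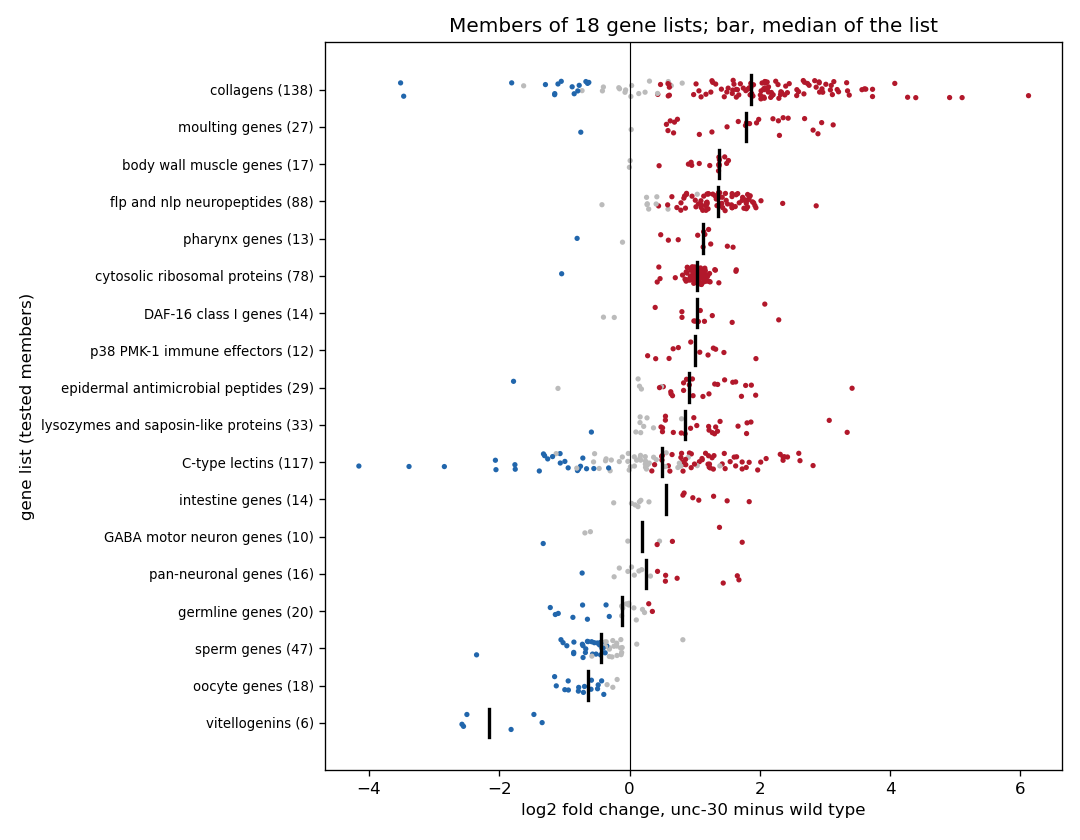
Log2 fold change (unc-30 minus wild type, TMM scaling) of the tested members of 18 gene lists, 1 point per gene, red called higher, blue called lower and grey not called; black bars are list medians and ttr-39, with 0 reads in the mutant, is not drawn. Medians run from -2.16 for vitellogenins to 1.87 for collagens, and muscle scaling moves the median of all genes by -1.08.

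Cuticle genes showed the highest list medians. Of 138 collagen genes, 106 were higher and 15 lower (median 1.87, camera adjusted p = 4.77e-40, adjusted p = 0.123 with an estimated correlation). Of 27 moulting genes, 25 were higher and 1 lower (median 1.79, camera adjusted p = 8.84e-19, adjusted p = 0.266 with an estimated correlation), and both medians stayed above 0 under each scaling, with 88 collagens higher and 36 lower and 16 moulting genes higher and 7 lower with muscle scaling. The collagen genes col-176 and col-41 rose by 4.91 ± 0.18 and 4.39 ± 0.20 (SE). Members col-166 to col-170, neighbours on chromosome X that may share reads, rose by 3.37 to 4.27. The matrix genes lpr-3 and noah-2 rose by 3.12 ± 0.18 and 2.95 ± 0.15, while col-135 fell by 3.51 (SE 0.28). Among called genes of at least 5 CPM whose groups did not overlap, the largest increase was in gmd-2 at 5.33 ± 0.36, and large decreases outside collagens and lectins included T22B7.7, ZK354.3 and C17F3.3, at -3.73, -3.33 and -3.27.

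Oocyte and sperm genes were lower under each scaling. Oocyte genes had 15 lower of 18 and 0 higher (median -0.64, camera adjusted p = 0.00501, adjusted p = 0.626 with an estimated correlation), and the eggshell gene perm-2 fell from 333 ± 37.3 to 150 ± 30.6 CPM (SD, n = 3 each). Sperm genes had 27 lower of 47 and 0 higher (median -0.44, camera adjusted p = 0.00351, adjusted p = 0.676 with an estimated correlation). The sperm median was -0.24 without unc-30 replicate 2 and -0.94 with library totals, where 45 were lower, and spe-11 fell by 2.35 (SE 0.20). Genes of the proliferating and meiotic germ line had 2 higher and 8 lower of 20 (median -0.11, camera adjusted p = 0.095, adjusted p = 0.00828 with library totals), against 0 and 18 with library totals (median -0.62), 0 and 20 with intestine (median -0.76) and 0 and 20 with muscle scaling (median -1.19), with the synaptonemal complex gene syp-1 down by a log2 change of -1.22 (SE 0.13). Cytosolic ribosomal protein genes had 77 higher and 1 lower of 78 under TMM (median 1.04, camera adjusted p = 5.59e-25, adjusted p = 0.367 with an estimated correlation), but 2 higher and 6 lower with muscle scaling (median -0.04). Histone genes had 20 higher and 4 lower of 34 (median 0.64, camera adjusted p = 0.00596, adjusted p = 0.55 with an estimated correlation), at -0.01 with intestine and -0.44 with muscle scaling, where 4 were higher and 13 lower.

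**Figure D3:**
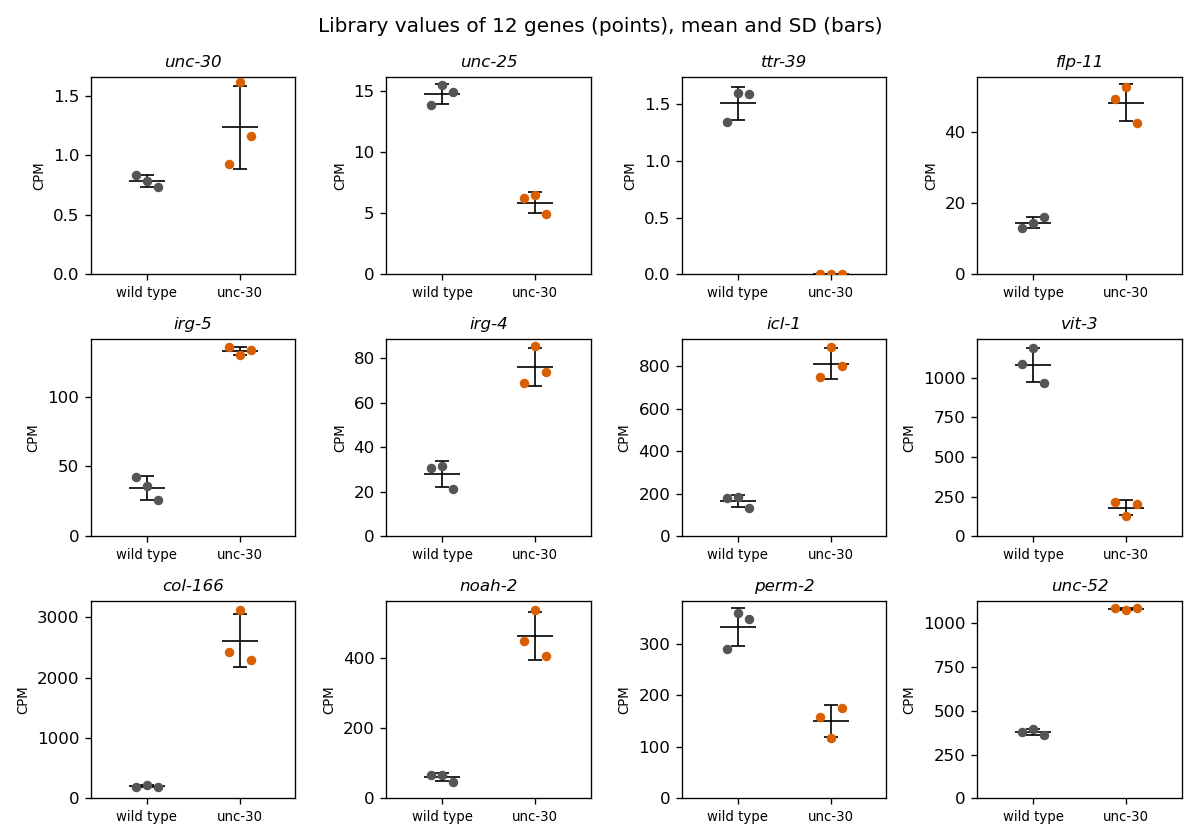
CPM of 12 genes in each library (points), with the mean and SD of 3 libraries per genotype (bars); each axis starts at 0. For unc-25 the unc-30 libraries sit between 4.91 and 6.49 CPM and the wild-type libraries between 13.9 and 15.5, and for irg-5 between 130 and 135 against 25.8 and 42.3.

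All list calls under the preset correlation, 16 higher and 3 lower of 31, were lost with an estimated correlation, where 0 were called. Fry kept these calls apart from sperm and oocyte genes (fry adjusted p = 0.0691 and 0.0557). It asks whether a list moves on balance under TMM, not whether it moves more than the other genes. Counts of members adjusted over the list alone differed from those over all genes by at most 3 genes in each direction. For detoxification they were 44 higher and 23 lower, and for C-type lectins 56 higher and 23 lower.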

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

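The number of called genes lay between 8493 and 9162 when each library was left out in turn, and was 9444 with DESeq2 size factors, 9789 with no low-count filter, 8942 with DESeq2 and 9459 with limma-voom. It was 6089 with the stricter filter (2958 higher, 3131 lower), which tests fewer genes, and 4060 with a 2-fold limit (1867 higher, 2193 lower). Library totals gave 2090 higher and 8150 lower. Of the scalings chosen after seeing the data, intestine scaling gave 1611 and 8988, and muscle scaling 701 and 11407; these follow from the shift of all genes. No main call took the opposite direction with DESeq2, limma-voom or a library left out. Main calls turned to calls in the opposite direction numbered 103 with library totals, 346 with intestine scaling and 1796 with muscle scaling. With the replicate block, 9014 genes were called. Same-numbered libraries deviated with correlations of -0.102, 0.0237 and -0.0305, so the numbers were not treated as pairs, and no unc-30 library correlated best with its own number. The block ended the call of pan-neuronal genes (adjusted p = 0.0516) and of 3 named genes.

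With an estimated correlation 0 lists were called, against 19. The adjusted p was then 0.312 for PMK-1 effectors, lysozymes, C-type lectins, vitellogenins, neuropeptides and insulin-like genes, 0.44 for epidermal peptides, 0.266 for DAF-16 class I genes and 0.516 for endoplasmic reticulum stress. Fry, which asks only whether a list moves on balance, called GABA receptors (0.00526), the ZIP-2 list (0.00281), pals (0.0386), fatty acid synthesis (0.023) and lipid breakdown (0.00472), and ended the calls of sperm genes (0.0691) and oocyte genes (0.0557). With library totals, the adjusted p was 0.0425 for the ZIP-2 list, 0.0403 for detoxification and 0.0926 for endoplasmic reticulum stress. With muscle and intestine scaling it was 0.0246 and 0.0422 for GABA receptors, 0.026 and 0.0413 for the ZIP-2 list, 0.0246 and 0.0413 for detoxification, and 0.463 and 0.21 for endoplasmic reticulum stress, each list pointing up against the other genes. Germ line genes were called with library totals (0.00828), no filter (0.038), muscle and intestine scaling (0.00575 and 0.0137) and fry (0.00744). Cholinergic genes were called, pointing up, in the same settings (0.0212, 0.0317, 0.00575, 0.0155 and 0.00695). Pan-neuronal genes were not called with muscle and intestine scaling (0.223 and 0.11), and fry called glutamate and monoamine genes (0.0208). With library totals, muscle and intestine scaling the sign of camera for the pals list turned up without a call (0.968, 0.588 and 0.902), while its own medians fell further, to -0.876, -1.44 and -1.01, with 0 members higher and 7, 14 and 8 lower. Lipid breakdown was called with no filter (0.0325) and with the stricter one (0.0485). With a library left out, medians ranged from -0.616 to -0.242 for sperm (-0.441 with all), 0.104 to 0.226 for detoxification (0.184), 0.0985 to 0.232 for GABA motor neurons (0.198), -0.164 to -0.0515 for germ line (-0.114), 0.0115 to 0.132 for fatty acid synthesis (0.0899), 0.221 to 0.396 for lipid breakdown (0.342), 0.0815 to 0.173 for endoplasmic reticulum stress (0.132) and -0.0935 to -0.044 for heat shock (-0.0566). The adjusted p was then 0.0499 to 0.133 for the ZIP-2 list and 0.0378 to 0.104 for lipid breakdown. The glutamate and monoamine list pointed down with the stricter filter (0.512). The cause was not tested.

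Of 124 named genes, 98 kept direction and side of the threshold under every alternative in which they were tested. Muscle scaling turned the log2 change of unc-30 to -0.403, gab-1 to -0.0238, dod-19 to -0.0264, dod-17 to -0.261, elo-4 to -0.347 and fasn-1 to -0.364. With library totals, muscle and intestine scaling, pals-22 was at -0.0118, -0.583 and -0.147, hsp-90 at -0.0955, -0.671 and -0.239, prg-1 at -0.158, -0.729 and -0.297, and fbf-2 at -0.206, -0.775 and -0.344. With muscle and intestine scaling hsp-1 was at -0.46 and -0.0272. These follow from the shift of all genes.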

Other observations

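The tests on gene families, on immune genes and on unc-25 and ttr-39 were chosen after the results were seen, and those on the number of changed genes before. Genes were also grouped by the family name in their symbol, without leaving out members of the fixed lists. The 186 families with at least 8 tested members were compared by camera. They include families that make up fixed lists, such as col, rpl, rps, nlp and flp, so their calls partly repeat those of the lists. There were 40 families higher and 13 lower, and none was called with an estimated correlation, where each family named here had an adjusted p of 0.626. Aspartyl protease genes (asp), of which asp-1 is also in the intestine list, had 10 of 11 higher (median 1.43, above 0 under each scaling, adjusted p = 1.21e-07). Patched-related genes (ptr) had 17 of 23 higher (median 0.93, adjusted p = 3.28e-06) and galectin genes (lec) 11 of 12 (median 0.95, adjusted p = 0.000192), with medians of -0.14 and -0.13 with muscle scaling. Genes named for a high incidence of males (him), many of which act in meiosis, had 9 of 11 lower (median -0.97, adjusted p = 0.00063). The integrator complex genes (ints) had 9 of 11 lower (median -0.69, adjusted p = 0.00786) and nonsense-mediated decay genes (smg) 7 of 9 (median -0.84, adjusted p = 0.0329), and the medians of these 3 families stayed below 0 under each scaling.

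Protein genes of the mitochondrial genome were higher in 12 of 12 cases (median 1, and -0.08 with muscle scaling), and mitochondrial reads made up 2.08 ± 0.176% of unc-30 and 1.52 ± 0.0872% of wild-type reads (SD, n = 3 each). Annotated pseudogenes went the other way, with 262 lower and 24 higher of 476 (median -0.80, below 0 under each scaling). Genes on chromosome X had 879 higher and 402 lower of 2094, with a median of 0.32 that turned to -0.18 with library totals, -0.32 with intestine and -0.75 with muscle scaling. Those on chromosome I had a median of -0.16, below 0 under each scaling. The male list had too few members past the low-count filter and was not called without it (median 0.706, camera adjusted p = 0.391); its member mab-3 had 131, 197 and 119 reads in unc-30 and 71, 65 and 45 in wild type. Besides ttr-39, 3 called genes had 0 reads in a whole group, T22B2.1 and fbxc-28 in unc-30 and ZK488.5 in wild type, with bounds of at least 13.7-fold and 10.8-fold lower and at least 33.9-fold higher. These genes were chosen after their values were seen.

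The breadth of the change, 9457 called genes, may reflect a difference in developmental stage between the cultures. All 5 lists that track stage (collagens, moulting, sperm, oocyte, vitellogenins) were shifted with the preset correlation, though none with an estimated one, and their members had a median absolute log2 change of 1.33 against 0.595 for all genes. Genes within 2 Mb of unc-30 on chromosome IV were called with an odds ratio of 1.09 (95% interval 0.916 to 1.3, Fisher's exact test). Calls thus showed no clear excess near unc-30. The window held only 595 of 14788 tested genes, so it could not hold most of the calls whatever the ratio. The ratio also cannot speak to a linked variant acting on distant genes, which would not raise it. Whether wild type was further along stays open on the collagens chosen for it: adult-stage minus furrow collagens gave -2.45, but only col-19 of 3 adult-stage genes was lower. Of the other stage lists, vitellogenin genes (6 of 6 lower in unc-30) and oocyte genes (15 of 18 lower) went the way a further-along wild type would have it. Sperm genes were lower as well (27 of 47, 0 higher), and no direction by stage was set for any of these lists beforehand. The furrow collagens (0 of 6 lower, median 2.87) are part of the difference above and add no separate evidence. Stage goes with genotype in every library here, so a delay that the mutation itself causes stays open as well.

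Of 10 splits of the libraries, 1, the real one, called as many genes, the highest other called 0 (edgeR; at most 147 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.

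The rise of immune genes in unc-30 could come from a larger share of somatic RNA. Whether all somatic tissues rose alike was not settled. Muscle, pharynx, intestine and pan-neuronal genes moved apart, with means of 1.07, 0.84, 0.64 and 0.42, all higher (permutation p = 0.0255, 100000 resamples). That permutation shuffled genes as if independent, while estimated correlations within these lists were 0.525, 0.442, 0.108 and 0.141. The PMK-1 effectors, at a mean of 0.993, lay within the range of those means, as such a rise would have it. A larger share of intestine RNA alone stays open: PMK-1 effectors exceeded intestine genes by 0.355 on average (95% bootstrap interval -0.0619 to 0.766; two-sided permutation p = 0.126). This interval and p-value also treat genes as independent, while the estimated correlations were 0.279 for PMK-1 effectors and 0.108 for intestine genes. Without uninfected libraries, a difference in basal level and a difference in the response to infection were not separated.

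Lower unc-25 and ttr-39 may reflect the loss of UNC-30 activity in D-type neurons, which was not tested apart from genotype. A lower share of neuronal RNA is argued against for unc-25, since 1 of 35 other neuronal genes, tbh-1, had a change as low. By annotation, a variant near unc-30 cannot lie at unc-25, which is on chromosome III (0 matches on chromosome IV). A variant that lowers unc-25 from a distance, or elsewhere in the strain, was not tested. A linked variant at the gene itself stays open for ttr-39, which lies on chromosome IV at 10088367 to 10089877 (WBcel235), 3.03 Mb from unc-30. Its 0 reads could also come from a deletion in the strain.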
